A study of Danio rerio with 4 samples.

How the data were processed

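Retinas of wild type zebrafish and of zebrafish mutant for both csf1ra and csf1rb were injured by NMDA injection into the eye and collected 2 days later, per the labels' protocols (about 0.5 microliters of 100 mM NMDA). NMDA is a glutamate receptor agonist that damages neurons of the inner retina. Cells of 10 retinas per genotype were dissociated with papain after overnight dark adaptation and passed through a 30 micron filter, and droplet libraries were made with a 3' single-cell kit that tags each RNA molecule with a unique molecular identifier (UMI). The labels name 2 libraries per genotype. They do not say whether the libraries of a genotype came from separate pools of fish, so the p-values measure only the spread between these libraries, which may be technical. The labels give no sequencing batch or date, so a batch that follows genotype cannot be told apart from genotype.

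The deposited values are raw UMI counts per gene and barcode. They were made with Cell Ranger 9.0.1 per the file headers, whereas the submitters' processing notes name Cell Ranger 10, and the genome build is GRCz11 per those notes. The annotation release is not given in the sources used here. The deposited barcodes had at least 500 UMIs each, so they had already been filtered to cells. The 26279 features include an enhanced green fluorescent protein sequence that had 0 UMIs in every library. Gene symbols and identifiers are those of the deposited files, and a reference table of another assembly (GRCz12tu) served only to find which genes neighbour each other, so no coordinates are given. A 3' tag is counted near the end of a transcript, so a mutation elsewhere in a gene need not change its count.

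Total depth was 218406619 and 207895413 UMIs in the WT libraries and 208448731 and 225125431 UMIs in the mutant libraries. These held 23325, 22108, 24425 and 24256 barcodes with median depths of 2816, 2874, 2805 and 3030 UMIs. Barcodes with under 200 genes or over 20% mitochondrial UMIs were removed, which left 18706, 17550, 20001 and 19842. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0.465%, 0.336%, 0.655% and 0.262% of barcodes, which was taken as a failure of that threshold, and the highest-scoring barcodes were removed instead at 0.8% per 1000 barcodes. This took out 15.0%, 14.0%, 16.0% and 15.9% and kept 15907, 15086, 16801 and 16692 cells. The removal reached 28.7% of ganglion-like and 29.2% of neutrophil-like barcodes but 5.49% of bipolar-like and 7.51% of rod-like ones. It took 23.4% of Müller glia-like and 24.2% of cycling progenitor-like barcodes. In a chi-square comparison of counts over genes, the WT libraries differed from each other by 19.4 per degree of freedom and the mutant libraries by 12.0, so no library was a copy of another.

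Counts were scaled to 10000 UMIs per cell and logged, 2000 variable genes were reduced to 30 principal components, and cells of all libraries were clustered together without integration (15 neighbours, Leiden resolution 1.0, igraph 0.11.9). Each of the 47 clusters was named from 19 marker lists fixed before the data were examined. A name needed at least 3 detected markers, meaning genes in at least 10% of the cluster's cells and at least 2-fold above the 25th percentile of all clusters. A cluster stayed unnamed if its top 10 genes by fold held more markers of another class than of its own, if its cells had a median UMI count more than 3 times below that of their library with no own marker on top, or if over 90% of its cells came from 1 library. The rule on markers of another class was applied after the clusters had been seen. In this way 42 clusters were named, in 13 classes. The unnamed clusters held 9.98% ± 0.110 (SD, n = 2) of WT cells and 7.97% ± 0.324 of mutant cells, most of them in a low-UMI cluster with 8.98% and 8.93% of WT and 5.41% and 6.04% of mutant cells. Cluster 40, kept out of a class for its markers, held 0.453% and 0.457% of WT and 0.756% and 0.689% of mutant cells. Cluster 43 held 0.245% and 0.192% against 0.994% and 1.03%, and cluster 45 held 0.138% and 0.318% against 0.571% and 0.431%.

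The Müller glia lineage was defined as the Müller glia-like clusters together with the cycling progenitor-like clusters, so that dividing cells were not split off from it. UMI counts were summed per library and class, and genotypes were compared with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM normalisation, filterByExpr) in the lineage, in each other class with at least 50 cells in every library, and over all cells. Adjusted p-values are Benjamini-Hochberg over genes, called at 0.05. Fold changes are mutant over WT, CPM values are UMIs scaled by the TMM-normalised library size, and errors of CPM and shares are SD over n = 2 libraries. Cell numbers per class were compared with the same edgeR test, with the library's total as offset. Whether the genotype effect differed between the lineage and all other cells was tested as an interaction with library as a block. Exact permutation tests of 2 against 2 libraries cannot give a two-sided p below 0.333. Intervals of single-library shares are 95% exact binomial (Clopper-Pearson) and cover counting error only.

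Also fixed beforehand were 19 gene lists: DNA replication, mitosis, cell cycle regulators, retina regeneration, Müller glia identity, Notch pathway, JAK-STAT cytokine signalling, interferon response, inflammatory mediators, microglia markers, rod markers, cone markers, immediate early and heat shock genes, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis, phagocytosis and lysosome, extracellular matrix, and growth factor and Wnt signalling. They were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists. Named genes follow a rule fixed beforehand. In the lineage it takes the 10 with the smallest p each way among called genes with at least 10 CPM in a genotype's mean and no overlap between genotypes, up to 3 called members of each called list, and a fixed set of division, regeneration and glial genes. In other classes, over all cells and for the interaction it takes 3 each way, and it takes csf1ra and csf1rb always. A gene that the rule takes is not reported here. Clone-like names were passed over, and the pattern for such names was extended by a few prefixes after the first names had been seen. Counts of genes with near-identical relatives (hsp70l and hsp70.2, the her4, ms4a17a, dicp1, lgals9l and ccl34b families, and the exosc3 entries) can be split between copies and are uncertain.

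To compare the share of cells with a UMI of pcna, mcm5, mki67, top2a, cdk1 or ccnb1, each cell was thinned to 1000 UMIs and shallower cells were left out. Alternatives covered normalisation, filters, doublet removal, thinning, resolution, lineage membership, a replicate block, DESeq2 1.42.0, and leaving out each library. The fits were tested on simulated counts with known answers, drawn from the real means and library sizes. Genes were drawn independently of each other and with the same dispersion for all. For the lineage comparison of 18987 genes, edgeR recovered 15 of 48 genes changed 1.25-fold, 33 of 48 changed 1.5-fold, 47 of 49 changed 2-fold and 49 of 49 changed 4-fold, and called 6 unchanged genes. DESeq2 recovered 2, 25, 40 and 44 of 50 genes at those folds over 24110 genes, with 1 unchanged gene called. The interaction test recovered 154 of 199 genes changed 2-fold among 21628, with 12 unchanged genes called. Both of 2 changed lists were called with either correlation over 19012 genes, and no unchanged list was called with the preset one. Since the simulated genes were not correlated, this does not show how either setting behaves on correlated genes. For cell numbers, 57 of 60 changed classes and 1 of 220 unchanged classes were called. Classes were drawn independently with the real totals as offset, so a changed class did not move the shares of the others. In real shares it does, and the simulation does not show how often unchanged classes are then called. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3.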

Results

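Single-cell RNA-seq was done on zebrafish retinas collected 2 days after NMDA had been injected into the eye, from wild type (WT) fish and from fish carrying mutations in both csf1ra and csf1rb. These genes encode the zebrafish receptors for colony-stimulating factor 1, which microglia and other macrophages depend on. Müller glia, the radial glia of the retina, re-enter the cell cycle after such an injury and give rise to progenitors that replace lost neurons. The stated subject of the study is the crosstalk between microglia and Müller glia and the processes in Müller glia that go with cell division. There were 2 libraries per genotype, with 15907 and 15086 WT cells and 16801 and 16692 mutant cells after filtering. Total depth ran from 207895413 to 225125431 UMIs per library. Fold changes below are mutant over WT from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values, and errors are the standard error of a log2 fold or the SD of n = 2 libraries. Numbers of higher and lower genes always refer to the mutant.

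The mutated genes were looked at first. Over all cells, csf1rb (ENSDARG00000053624) had 5373 and 4900 UMIs in the WT libraries and 148 and 157 in the mutant libraries. Its level fell from 40.2 CPM ± 1.93 to 1.21 ± 0.0180 (log2 fold −5.06, SE 0.06, adjusted p = 6.42e-09). csf1ra (ENSDARG00000102986) had 3139 and 2939 UMIs in WT and 643 and 683 in mutants. It fell from 23.8 CPM ± 0.701 to 5.25 ± 0.0734 (log2 fold −2.18, SE 0.05, adjusted p = 3.35e-08). In WT, 2981 and 2789 of the csf1ra and 5318 and 4843 of the csf1rb UMIs came from microglia-like cells, whose number differed between genotypes. In mutants it was 202 and 284 for csf1ra, with 201 and 175 from the Müller glia lineage, and 90 and 105 for csf1rb. Within the microglia-like class, csf1rb was 174.6 CPM ± 0.297 in WT and 38.62 ± 3.82 in mutants (log2 fold −2.18, SE 0.09, adjusted p = 2.11e-07). csf1ra was at 99.2 CPM ± 1.73 in WT and 96.2 ± 22.0 in mutants of that class (log2 fold −0.04, SE 0.12, adjusted p = 0.837). That fold became 0.14 without mutant replicate 1 and −0.32, past the threshold, without mutant replicate 2. A tag at the 3' end need not report a mutation elsewhere in the transcript, so these counts do not test the genotype by themselves.

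The first comparison asked which cell classes the retina held in each genotype. Microglia-like cells, named from markers such as mpeg1.1, the c1q genes and apoc1, made up 8.93% ± 0.446 of WT cells and 0.570% ± 0.0185 of mutant cells, a 15.6-fold lower share (log2 fold −3.97, SE 0.08, adjusted p = 9.28e-07). The log2 fold was −3.11 at clustering resolution 2 and −3.23 with no doublets removed. In single libraries the shares were 9.25% (95% interval 8.80 to 9.71) and 8.62% (8.17 to 9.08) in WT, from 1471 and 1300 cells, and 0.583% (0.474 to 0.710) and 0.557% (0.450 to 0.682) in mutants, from 98 and 93 cells. Of 2 microglia-like clusters, 1 held 1151 and 972 WT cells and 97 and 90 mutant cells, and the other held 320 and 328 WT cells against 1 and 3 mutant cells. Neutrophil-like cells moved the other way, from 0.181% ± 0.00236 to 0.645% ± 0.0646 (log2 fold 1.83, SE 0.15, adjusted p = 0.000166), but at clustering resolution 2 the log2 fold was 0.58 and no longer passed (adjusted p = 0.0530). The 2 weaker folds at resolution 2 may come from the same cells, since neutrophil-like cells went from 29 and 27 in WT and 116 and 100 in mutants to 20 and 17 and to 29 and 31, while microglia-like cells of mutants rose in number. A microglia-like cluster there, cluster 28, had grn1, grn2 and spink2.2 among its leading genes, as the neutrophil-like cluster had at resolution 1.

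Bipolar-like, ganglion-like and amacrine-like neurons took larger shares of the mutant libraries. Bipolar-like cells rose 2.64-fold, from 11.9% ± 0.00895 to 31.5% ± 0.319 (log2 fold 1.40, SE 0.03, adjusted p = 1.50e-06). Ganglion-like cells rose from 0.967% ± 0.114 to 2.65% ± 0.105 (log2 fold 1.45) and amacrine-like cells from 8.03% ± 0.0361 to 12.2% ± 0.0308 (log2 fold 0.60), each with an adjusted p of 6.50e-05. Photoreceptors fell, with rod-like cells at 19.9% ± 0.412 in WT and 12.9% ± 0.312 in mutants (log2 fold −0.62, adjusted p = 6.50e-05). Cone-like cells were at 10.7% ± 1.01 and 5.66% ± 0.164 (log2 fold −0.92, adjusted p = 0.000166), and rod precursor-like cells at 1.47% ± 0.137 and 0.776% ± 0.0627 (log2 fold −0.92, adjusted p = 0.000786). The fall of rod-like cells lay in cluster 6 (1299 and 1247 WT cells, 535 and 630 mutant cells) and cluster 7 (630 and 538 against 333 and 269), while cluster 11 held 1187 and 1258 WT and 1343 and 1224 mutant cells. Cells like the retinal pigment epithelium fell from 0.377% ± 0.0178 to 0.158% ± 0.0387 (log2 fold −1.25, adjusted p = 0.00194). Müller glia-like cells fell from 4.29% ± 0.0583 to 3.09% ± 0.256 (log2 fold −0.47, SE 0.07, adjusted p = 0.00166). Cycling progenitor-like cells were 13.3% ± 1.23 of WT and 12.7% ± 0.257 of mutant cells (log2 fold −0.08, SE 0.07, adjusted p = 0.336). This count leaves out the unnamed low-UMI cluster 1, with 1428 and 1347 WT and 909 and 1009 mutant cells. Its best marker list was that of cycling progenitors, and the glial markers fabp7a and gfap were among its top genes. At resolution 2, a low-UMI cluster of 918 and 824 WT and 405 and 519 mutant cells was named cycling progenitor-like. The direction of the cycling progenitor-like class depended on the setting, with 0.22 (adjusted p = 0.000889) when classes were scaled by TMM in place of the total and 0.14 (0.00778) with no doublets removed. It was −0.31 (0.00193) without photoreceptors in the total, −0.31 (0.0104) at resolution 2, −0.18 (0.0134) with a minimum of 500 genes and −0.17 (0.00275) without WT replicate 1. Horizontal-like cells were at 9.37% ± 0.265 and 8.51% ± 0.212 (log2 fold −0.14, adjusted p = 0.0313), a direction that turned to 0.16 (0.0182) with TMM over classes. The call was lost without WT replicate 1 (adjusted p = 0.0667), mutant replicate 1 (0.113) or mutant replicate 2 (0.0584). Oligodendrocyte-like cells were at 0.516% ± 0.0263 and 0.633% ± 0.104 (log2 fold 0.29, adjusted p = 0.122). They were called higher with TMM over classes (0.59, adjusted p = 0.000938) and without mutant replicate 1 (0.45, adjusted p = 0.0254), and the sign turned with doublets removed at 0.4% per 1000 barcodes (−0.11), a setting added after seeing the data.

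Shares are parts of a whole, so a change in 1 class moves the others, and genotype differences in the genes used for clustering can move cells between classes. When cells were clustered without 6704 genes that differed between genotypes, an alternative added after seeing the data, the log2 folds were −2.88 for microglia-like, 1.39 for bipolar-like, 1.47 for ganglion-like, 0.61 for amacrine-like, −0.63 for rod-like, −0.92 for cone-like and −0.20 for Müller glia-like cells. In that clustering no neutrophil-like class formed.

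**Figure D1:**
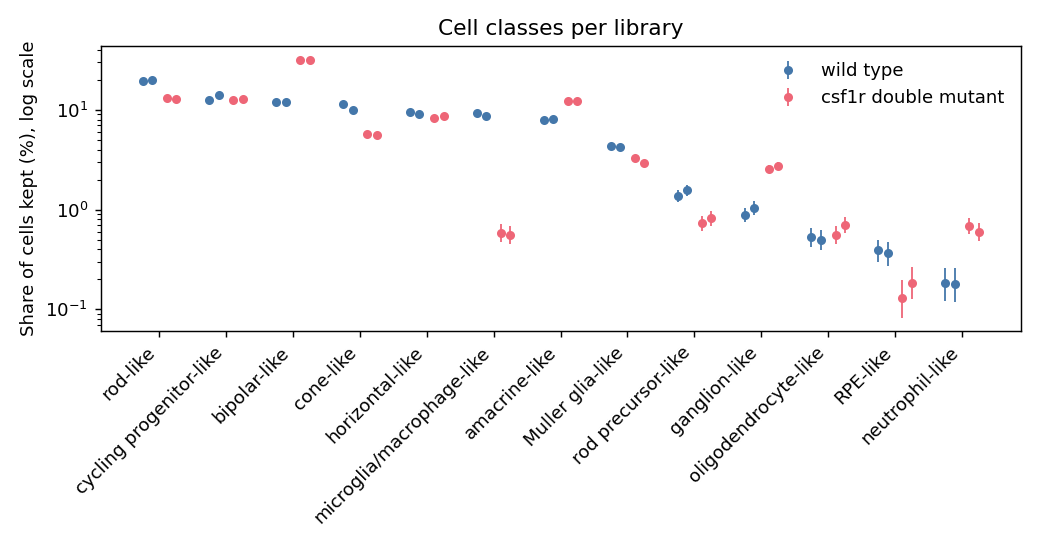
Share of cells per class (percent of all kept cells, log axis) in each WT and mutant library, with 95% exact binomial intervals that cover counting error only. Microglia-like cells lie at 9.25% and 8.62% in the WT libraries and at 0.583% and 0.557% in the mutant libraries, and bipolar-like cells lie higher in both mutant libraries.

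The central comparison asked how cell division and gene expression in the Müller glia lineage differed without these receptors. Genes that mark dividing cells were at like levels in both genotypes in the lineage as a whole, that is, the Müller glia-like and cycling progenitor-like cells together. Clusters joined this lineage in part on such genes, so their levels in it are not an independent measure of division. The unnamed low-UMI cluster, whose best marker list was that of cycling progenitors, was not part of the lineage. The proliferation marker mki67 was at 252.0 CPM ± 20.9 in WT and 260.3 ± 21.6 in mutants (log2 fold 0.05, SE 0.07, adjusted p = 0.631). The gene of the sliding clamp of DNA replication, pcna, was at 1087 ± 70.6 and 1091 ± 6.34 (log2 fold 0.01, SE 0.05, adjusted p = 0.940). The topoisomerase gene top2a (log2 fold 0.09, adjusted p = 0.192) and the mitotic kinase gene cdk1 (log2 fold 0.05, adjusted p = 0.474) did not pass the test either. The helicase gene mcm5 fell slightly (log2 fold −0.17, SE 0.05, adjusted p = 0.0134; 0.126 without mutant replicate 1), but was at 0.01 with cells thinned to 1000 UMIs. Of 51 measured DNA replication genes, 10 were higher and 7 lower (10 and 6 adjusted over the list alone). Of 64 mitosis genes, 10 were higher and 7 lower (6 and 4 adjusted over the list alone). Neither list passed the camera test (median log2 fold 0.06, adjusted p = 0.583, and 0.07, adjusted p = 0.383), nor did they with an estimated correlation (adjusted p = 0.905 for both).

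The share of lineage cells with at least 1 UMI of pcna, mcm5, mki67, top2a, cdk1 or ccnb1 was then compared, since summed counts can be carried by a few cells. All of these genes were also markers used to name the cycling progenitor-like clusters. Clusters joined the lineage in part on these genes, so this share is not an independent measure of division either. With every cell thinned to 1000 UMIs, it was 61.5% (95% interval 59.4 to 63.5) and 63.1% (61.1 to 65.0) in the WT libraries and 64.4% (62.3 to 66.4) and 62.5% (60.4 to 64.6) in the mutant libraries. The means were 62.3% ± 1.12 and 63.4% ± 1.35 (exact permutation p = 0.667, two-sided, where 0.333 is the smallest possible). Thinning left out 433 and 479 WT and 515 and 524 mutant lineage cells, and without thinning the means were 80.8% and 80.4%. In rod-like cells, a class that should lack these transcripts, the thinned shares were 7.56% and 8.18% in WT and 7.99% and 8.49% in mutants. Median depths before thinning were 11479 and 11352 UMIs in WT and 10510 and 10113 in mutants for the lineage cells kept, and between 2000 and 2187 for rod-like cells.

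**Figure D2:**
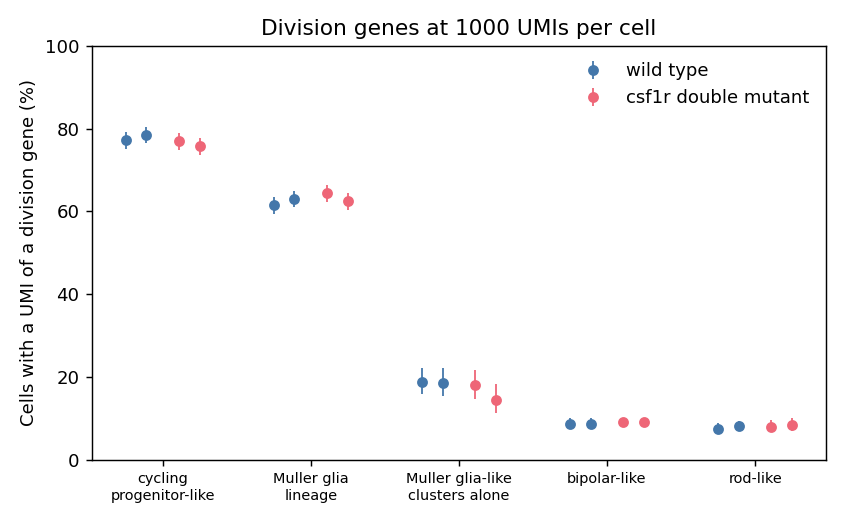
Share of cells (percent) with a UMI of any of 6 division genes after thinning each cell to 1000 UMIs, per library, with 95% exact binomial intervals for counting error. Cycling progenitor-like cells lie between 75.7% and 78.6%, the lineage between 61.5% and 64.4%, Müller glia-like clusters alone between 14.6% and 18.9%, and rod-like and bipolar-like cells between 7.56% and 9.19%.

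Beyond division genes, the lineage differed widely between genotypes. The lineage held 2674 and 2786 WT cells and 2647 and 2630 mutant cells, with 43380197 to 48129679 UMIs per library. Of 19088 genes tested, 4037 were higher and 3925 lower, and 1957 of these changed more than 2-fold. The number of called genes was 1661 against a minimum fold of 1.5, 1850 with cells thinned to 1000 UMIs, 5166 with DESeq2 and 11979 with no doublets removed. Among the most clearly changed genes, anxa2a (ENSDARG00000003216), which encodes the calcium- and membrane-binding annexin A2, rose 24.0-fold from 49.3 CPM ± 0.269 to 1185 ± 73.3 (log2 fold 4.59, SE 0.06, adjusted p = 8.75e-13). The rgs5b gene, a regulator of G-protein signalling, rose from 86.2 CPM ± 1.96 to 299.8 ± 18.1 (log2 fold 1.80, adjusted p = 6.46e-10). The genes faub (log2 fold 3.26), kng1 (2.22), lgals17 (5.41) and fundc2 (1.62) rose as well, each with an adjusted p of 1.27e-09 or below. In the other direction, htr7c (ENSDARG00000095272), a serotonin receptor gene, fell from 128.9 CPM ± 7.35 to 6.32 ± 0.528 (log2 fold −4.35, SE 0.07, adjusted p = 8.23e-12). Also lower were ctsba, which encodes cathepsin B (log2 fold −2.86, SE 0.06, adjusted p = 3.21e-11), phb2a, a prohibitin gene (−2.46), the retinoic acid-binding protein gene crabp2a (−2.04), fabp11a (−2.99) and the glutathione transferase genes gsta.1 (−2.08) and gstt1a (−3.34). Of these, fabp11a was at 16349.5 CPM and ctsba at 3132 CPM in WT microglia-like cells, whose markers also fell in the lineage. However, ctsba and phb2a fell over 2-fold in all 10 tested classes, microglia-like cells included, so their fall was not particular to the lineage. Lineage cells of the genotypes also lay in part in different clusters. When they were clustered without division genes, the alternative added after seeing the data, 1 cluster held 453 and 470 WT and 24 and 20 mutant cells and another 731 and 639 against 104 and 129. On the other side were clusters of 8 and 7 against 380 and 360 cells and of 46 and 155 against 746 and 760.

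Interferon response genes rose together in the mutant lineage: of 36 measured, 29 were higher and 4 lower (29 and 4 adjusted over the list alone), with a median log2 fold of 0.93 (camera adjusted p = 3.05e-08; adjusted p = 0.440 with an estimated correlation). The antiviral genes ifit8 and mxa went from 0.329 CPM ± 0.0191 to 21.6 ± 0.978 (log2 fold 6.03, SE 0.13, adjusted p = 5.79e-11) and from 0.237 ± 0.110 to 18.8 ± 0.858 (log2 fold 6.27, SE 0.17, adjusted p = 3.34e-10). The signal transducer gene stat1b rose with a log2 fold of 4.70 (SE 0.15, adjusted p = 1.24e-09), and dhx58, a member of the RNA-sensing helicase family, with one of 3.09 (SE 0.10, adjusted p = 1.40e-09). Of 35 genes of JAK-STAT cytokine signalling, 20 were higher and 5 lower (22 and 6 adjusted over the list alone; median 0.26, camera adjusted p = 0.00631; adjusted p = 0.440 with an estimated correlation). Among them socs1a, an inhibitor of cytokine signalling, rose (log2 fold 1.79, SE 0.13), as did junba (0.76, SE 0.05), while the receptor gene lepr fell (−0.72, SE 0.05). The transcription factor gene stat3 rose slightly (log2 fold 0.16, SE 0.05, adjusted p = 0.0160, but 0.136 without mutant replicate 2), and so did socs3a (0.23, adjusted p = 0.00223).

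Immediate early and heat shock genes were mostly higher, 28 of 43, with 4 lower (30 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.000344; adjusted p = 0.440 with an estimated correlation). The chaperone genes hsp70l (log2 fold 0.87, SE 0.05, adjusted p = 4.97e-08) and hsp70.2 (0.78, SE 0.05) rose, although counts may be split between these near-identical genes. The small heat shock gene hspb1 fell from 1859 CPM ± 2.54 to 715.1 ± 11.5 (log2 fold −1.38, SE 0.04, adjusted p = 1.13e-09). In the cycling progenitor-like clusters alone, a comparison added after seeing the data, this list no longer passed (adjusted p = 0.0785). Cell cycle regulators were higher for 19 of 37 genes and lower for 2 (19 and 2 adjusted over the list alone; median 0.19, camera adjusted p = 0.00631; adjusted p = 0.440 with an estimated correlation). In the Müller glia-like clusters alone this list turned to a median of −0.12 and did not pass (adjusted p = 0.721). The members with the smallest p-values encode inhibitors of cyclin-dependent kinases. Of these, cdkn1bb rose from 83.5 CPM ± 1.34 to 136.4 ± 3.72 (log2 fold 0.71, SE 0.05, adjusted p = 3.94e-07). Among the others cdkn1ba had a log2 fold of 1.29 (SE 0.11) and cdkn1ca 0.66 (SE 0.07). The cyclin gene ccnd1, which drives entry into the cycle, also rose (log2 fold 0.45, SE 0.05, adjusted p = 2.32e-05), but was at −0.26 (adjusted p = 0.0642) in the Müller glia-like clusters alone.

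Ribosome biogenesis genes fell together: 40 of 54 were lower and 1 higher (45 and 1 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 1.04e-08; adjusted p = 0.594 with an estimated correlation). Nucleophosmin, npm1a, fell from 1335 CPM ± 59.1 to 902.0 ± 22.6 (log2 fold −0.57, SE 0.05, adjusted p = 2.96e-06), imp3 had a log2 fold of −0.73 and rrp1 of −0.52. In glial clusters formed without division genes, an alternative added after seeing the data, this list turned and was higher for 33 of 53 genes and lower for 1 (34 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 3.54e-07; adjusted p = 0.367 with an estimated correlation). Müller glia identity genes were lower for 16 of 25 and higher for 5 (17 and 6 adjusted over the list alone; median −0.29, camera adjusted p = 0.0133; adjusted p = 0.594 with an estimated correlation). The retinoid-binding protein gene rlbp1a fell from 710.5 CPM ± 48.0 to 289.3 ± 23.5 (log2 fold −1.30, SE 0.06, adjusted p = 1.32e-07). The water channel gene aqp4 fell from 61.1 ± 5.67 to 21.0 ± 1.34 (log2 fold −1.54, SE 0.07) and dkk3b from 13.2 ± 0.780 to 1.43 ± 0.214 (log2 fold −3.20, SE 0.13). Glutamine synthetase, glula, fell as well (log2 fold −0.66, SE 0.06, adjusted p = 5.62e-06), as did gfap (−0.44, SE 0.05, adjusted p = 1.65e-05). The glial identity list also fell in the Müller glia-like clusters alone (12 of 25 lower and 5 higher, 15 and 5 adjusted over the list alone, median −0.23, camera adjusted p = 0.0364; adjusted p = 0.585 with an estimated correlation). It did not pass in the cycling progenitor-like clusters alone (median 0.08, mean −0.08, adjusted p = 0.715), where glula was at a log2 fold of 0.08.

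Markers of other cells also moved in the lineage. Of 37 microglia markers, 21 were lower and 4 higher (21 and 5 adjusted over the list alone; median −1.76, camera adjusted p = 0.000193; adjusted p = 0.440 with an estimated correlation), among them apoc1 (log2 fold −1.80), ccl34b.1 (−5.13) and lgals3bpb (−3.23). Their summed level in the lineage was 431 and 372 CPM in WT and 362 and 366 in mutants, against 105132 and 105533 CPM in WT microglia-like cells. Of 27 cone markers, 10 were lower and 0 higher (10 and 0 adjusted over the list alone; median −0.81, camera adjusted p = 0.000496; adjusted p = 0.622 with an estimated correlation), such as opn1sw1 (log2 fold −0.58), arr3b (−0.94) and guca1e (−1.69). With no barcodes removed as doublets opn1sw1 turned to a log2 fold of 0.48. Of 20 rod markers, 4 were higher and 6 lower (4 and 6 adjusted over the list alone; median −0.09, camera adjusted p = 0.421). In the Müller glia-like clusters alone rod markers turned and were called higher, with 4 of 19 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 0.0364; adjusted p = 0.783 with an estimated correlation).

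**Figure D3:**
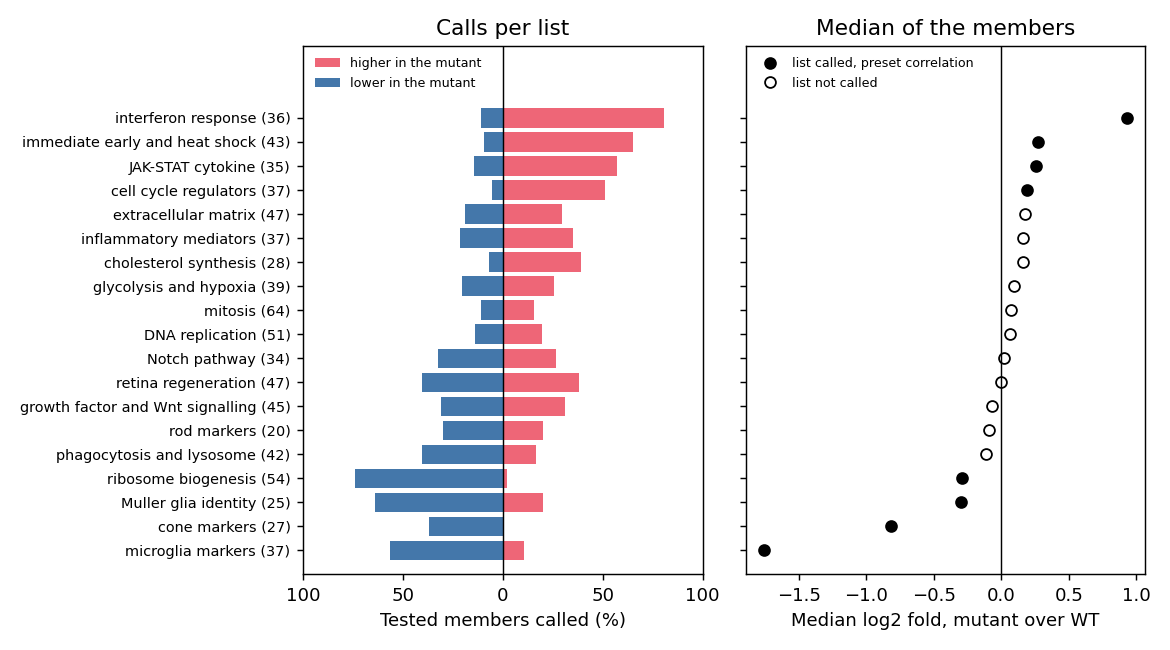
Gene lists in the Müller glia lineage: on the left the percent of each list's tested genes (their number in brackets) that were higher or lower in mutants, on the right the median log2 fold (mutant over WT), filled where camera called the list with a preset correlation. Interferon response has the highest median (0.93) and microglia markers the lowest (−1.76), and DNA replication and mitosis lie near 0.

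The remaining lists did not pass in the lineage. Retina regeneration genes split, with 18 of 47 higher and 19 lower (21 and 19 adjusted over the list alone; camera adjusted p = 0.897, testing towards higher with a mean of −0.03). Of the genes fixed beforehand, lin28a, an RNA-binding protein of reprogramming glia, rose from 584.0 CPM ± 15.3 to 796.2 ± 16.4 (log2 fold 0.45, SE 0.05, adjusted p = 1.28e-05), and hbegfa rose slightly (0.22, adjusted p = 0.00177). The proneural gene ascl1a fell slightly (log2 fold −0.15, SE 0.04, adjusted p = 0.0139, but 0.0726 and 0.102 without mutant replicate 1 or 2). Not past the threshold were sox2 (log2 fold 0.10), hmga1a (−0.00), insm1a (−0.19), mdka (0.03) and il34 (0.13), whose product is a ligand of the csf1 receptors. Another ligand gene, csf1a, was too low to judge (log2 fold −0.69, SE 0.32, adjusted p = 0.109), and csf1b had 2 and 1 UMIs in WT and 1 and 2 in mutants. Of 34 Notch pathway genes, 9 were higher and 11 lower (9 and 11 adjusted over the list alone; median 0.02 with the test towards lower, camera adjusted p = 0.872). The target genes her4.1 (log2 fold 1.13, SE 0.06, adjusted p = 3.33e-07) and her6 (0.43, SE 0.05) rose. Inflammatory mediators were higher for 13 of 37 and lower for 8 (15 and 9 adjusted over the list alone; median 0.16, adjusted p = 0.125). Phagocytosis and lysosome genes were higher for 7 of 42 and lower for 17 (7 and 17; median −0.11, adjusted p = 0.0978). Extracellular matrix genes were higher for 14 of 47 and lower for 9 (14 and 9; median 0.17, adjusted p = 0.271). Cholesterol synthesis genes were higher for 11 of 28 and lower for 2 (11 and 2; median 0.16, adjusted p = 0.271). Glycolysis and hypoxia genes were higher for 10 of 39 and lower for 8 (14 and 8; median 0.10, adjusted p = 0.283). Growth factor and Wnt genes were higher for 14 of 45 and lower for 14 (14 and 17; median −0.06, adjusted p = 0.326). In the last 5 lists the counts in brackets are those adjusted over the list alone.

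The lineage result joins cells of different states, so its parts were also compared. In the Müller glia-like clusters alone (689 and 641 WT cells, 550 and 486 mutant cells), mitosis genes fell for 35 of 60 and rose for 0 (42 and 0 adjusted over the list alone; median −0.998). DNA replication genes fell for 32 of 51 and rose for 0 (40 and 0; median −0.85). Each list had a camera adjusted p of 3.04e-12 (adjusted p = 0.604 and 0.610 with an estimated correlation). In these cells mki67 fell by 1.47 on the log2 scale (SE 0.20, adjusted p = 0.000320) and top2a by 1.65 (adjusted p = 0.000330). Inflammatory mediators were higher for 18 of 29 genes and lower for 5 (18 and 5 adjusted over the list alone; median 0.81, camera adjusted p = 4.90e-05; adjusted p = 0.585 with an estimated correlation). In the cycling progenitor-like clusters alone, the comparison added after seeing the data, neither division list passed (medians 0.02 for DNA replication and −0.00 for mitosis, adjusted p = 0.859 and 0.439). These clusters were named from division genes, so the levels of such genes there are not an independent measure of division. The larger of the 2 Müller glia-like clusters was cluster 16 in WT (56.2%) and cluster 4 in mutants (55.8%), but both clusters held many cells of each genotype. Cells of cluster 4 had a lower median depth than those of cluster 16. In the glial clusters formed without division genes, the medians turned to 0.53 for DNA replication and 1.30 for mitosis. That alternative left out 1593 genes and took in a cluster of 49 and 42 WT and 152 and 120 mutant cells, of which 32.0% had been Müller glia-like.

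The few microglia-like cells that were left in mutants differed in expression from those of WT. Of 14748 genes tested, 1686 were higher and 1618 lower, a count that fell to 1149 and 964 called genes without WT replicate 1 or 2. The class was not made up alike in the genotypes, since cluster 17 held 78.2% and 74.8% of its WT cells and 99.0% and 96.8% of its mutant cells. At resolution 2, a microglia-like cluster held 146 and 100 mutant cells against 257 and 228 WT cells, but this is the cluster 28 that shares leading genes with neutrophil-like cells, whose number in mutants fell from 116 and 100 to 29 and 31. The other microglia-like clusters held 8 to 23 mutant and 261 to 534 WT cells per library. Cathepsin Z, ctsz (ENSDARG00000043081), rose from 1156 CPM ± 11.5 to 2805 ± 16.3 (log2 fold 1.28, SE 0.04, adjusted p = 6.68e-08). Higher too were dicp1.17 (log2 fold 4.69) and ms4a17a.11 (3.41), members of families with close relatives. The glutathione transferase gene gsto2 fell from 1108 CPM ± 23.7 to 12.1 ± 2.96 (log2 fold −6.52, SE 0.11, adjusted p = 4.89e-10). Cathepsin B, ctsba (−2.29, SE 0.05), and the chemokine gene ccl34b.1 (−1.96, SE 0.05) fell too. Interferon response genes were higher for 22 of 35 and lower for 2 (23 and 2 adjusted over the list alone; median 0.73, camera adjusted p = 4.69e-07; adjusted p = 0.563 with an estimated correlation). Mitosis genes were lower for 29 of 63 and higher for 0 (34 and 0; median −0.36, camera adjusted p = 3.50e-07; adjusted p = 0.563 with an estimated correlation). DNA replication genes went the other way, with 8 of 51 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.13, camera adjusted p = 0.0244; adjusted p = 0.624 with an estimated correlation).

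Every other class with enough cells was compared in the same way, which asks whether the lineage differs from the rest of the retina. Interferon response genes were called higher in 8 of 9 other classes, with medians from 0.31 to 1.76 over the 9, and cone markers lower in 9, with medians from −1.42 to −0.20. Immediate early and heat shock genes were called higher in 6 and ribosome biogenesis genes lower in 5 and higher in 2. Microglia markers were lower in 5 and higher in 1, and their summed level in rod-like cells was 506 and 348 CPM in WT and 76.8 and 93.8 in mutants. No list was called with an estimated correlation in any class, where the lowest adjusted p was 0.297.

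Among inner retinal neurons, bipolar-like cells had 2585 genes higher and 2774 lower of 15803. The heat shock gene hsp70l rose in them from 149.5 CPM ± 4.098 to 576.6 ± 24.5 (log2 fold 1.95, SE 0.06, adjusted p = 2.74e-17), and hsp70.2 (1.39) and the prolyl hydroxylase subunit gene p4ha1b (2.11) rose too. Lower in them were gad2, which makes the transmitter GABA and was a naming marker of amacrine cells (−3.37), fabp11a (−5.05) and the peroxiredoxin gene prdx1 (−2.62). Microglia markers, whose clusters fabp11a also marks, fell with them in bipolar-like cells, from a summed 314 and 233 CPM in WT to 59.4 and 57.6 in mutants. The largest bipolar-like cluster was cluster 37 in WT (15.3%) and cluster 30 in mutants (11.7%). In mutants these 2 clusters were nearly equal in size, with 607 and 625 cells in cluster 30 and 632 and 589 in cluster 37. Amacrine-like cells had 3622 genes higher and 3732 lower of 16951. The interferon pathway gene stat2 rose there from 44.6 CPM ± 1.80 to 246.9 ± 8.03 (log2 fold 2.47, SE 0.06, adjusted p = 2.75e-09), with anxa2a (4.88) and lgals17 (6.35). In the same cells ctsba (−3.52), vmp1 (−1.39) and phb2a (−2.43) fell, and so did microglia markers (camera adjusted p = 0.00216; adjusted p = 0.412 with an estimated correlation). Ganglion-like cells had 834 genes higher and 721 lower of 13845, which became 748 and 689 called genes without mutant replicate 1 or 2. In these anxa2a (log2 fold 8.35, SE 0.25), ifi45 (2.03) and hsp70.2 (1.79) rose and ctsba fell (−2.99). In them the ferritin-like gene fthl30 had 67 and 62 UMIs in WT against 2 and 1 in mutants. Horizontal-like cells had 2749 genes higher and 2518 lower of 14438. Among them were prodha (log2 fold 2.49, SE 0.08), tpcn1 (1.74) and hsp70.2 (1.11) higher and fkbp5, a target of glucocorticoid signalling (−2.10, SE 0.06), naxe (−2.01) and slc25a18 (−1.54) lower.

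Among photoreceptors, cone-like cells had 2846 genes higher and 2961 lower of 15098. In cones igsf21a (log2 fold 3.26, SE 0.08), s100v2 (2.49) and fbxo32 (3.26) rose, and the nuclear receptor gene nr4a3 (−3.30, SE 0.07), arl3l2 (−1.65) and ctsba (−3.49) fell. Microglia markers, too, were called lower in cones (camera adjusted p = 0.000265; adjusted p = 0.534 with an estimated correlation). Rod-like cells had 1684 genes higher and 1575 lower of 12656, or 2116 called genes without WT replicate 2, and their largest cluster was cluster 6 in WT (41.3%) and cluster 11 in mutants (59.2%). In rods stm (log2 fold 4.99, SE 0.14), anxa2a (4.31) and recql4 (5.58) rose, and fabp11a (−4.87), sox11b (−1.82) and nr4a3 (−4.83) fell. Of these, stm was also among the top 10 genes of the cycling progenitor-like cluster 2, and RNA from such cells was not tested for it. Microglia markers fell in rods as well, with a median of −2.61 (camera adjusted p = 1.93e-10; adjusted p = 0.677 with an estimated correlation). Rod precursor-like cells had 168 genes higher and 144 lower of 10399, or 152 and 136 called genes without mutant replicate 1 or 2. The sodium pump gene atp1a3b (log2 fold 0.88, SE 0.07) and fundc2 (1.41) rose in them. Lower were fabp7a, a naming marker of Müller glia (−1.11, SE 0.07), sumo3b (−1.60) and phb2a (−2.12). For slc18b1 there were 1 and 0 UMIs in WT against 73 and 86 in mutants. Over all cells, 7552 genes were higher and 7455 lower of 22459, which includes the change in cell classes. There the chemokine gene ccl34b.1 fell from 1087 CPM ± 11.2 to 24.96 ± 0.647 (log2 fold −5.44, SE 0.05, adjusted p = 2.31e-09). Also over all cells, ctsba (−4.79) fell, and lgals17 (5.20), tex2l (2.23) and dhx58 (2.81) rose.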

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

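None of the tests in this part was chosen after its result was seen. The genotype effect differed between the Müller glia lineage and all other cells for 9635 of 21776 genes (edgeR quasi-likelihood interaction test with library as a block, Benjamini-Hochberg). The log2 fold, mutant over WT, was above that of the other cells for 5083 of these genes and below it for 4552. The other cells include classes whose shares changed, such as microglia-like and photoreceptor-like cells, which fell, and bipolar-like cells, which rose. A gene of such a class moves there with the number of its cells, and the counts of genes given here were not corrected for this. Against rod-like cells alone, the count was 2438 of 18939 genes, with 1078 above and 1360 below.

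The genes with the smallest p each way follow, as the difference of the log2 folds, lineage minus other cells. The galectin gene lgals9l3 had a difference of 5.36 (SE 0.08, adjusted p = 1.06e-10), going from 8.09 CPM ± 0.381 in WT to 31.6 ± 1.82 in mutants in the lineage and from 186.3 ± 2.03 to 17.7 ± 1.37 in the other cells. The cholesterol transport gene npc2 had one of 3.26 (SE 0.05), with 139.7 and 147.9 CPM in the lineage but 847.4 and 93.4 in the other cells. The transcription factor gene jdp2b had one of 3.05 (SE 0.07), going from 138.5 to 213.5 CPM in the lineage and from 181.6 to 33.9 in the other cells. In the other direction, the serotonin receptor gene htr7c had a difference of −5.19 (SE 0.11), going from 149.2 to 7.20 CPM in the lineage against 13.7 and 24.1 in the other cells. For ca10a, a carbonic anhydrase-related gene, it was −2.76 (SE 0.07), with 42.3 and 12.1 CPM in the lineage against 105.5 and 205.4 in the other cells. This gene was among the top 10 of the unnamed clusters 40 and 45, which held larger shares in mutants and had bipolar as their best marker list. For the growth factor gene mdkb the difference was −1.84 (SE 0.05), with 301.4 and 184.2 CPM in the lineage against 214.6 and 468.9 in the other cells. All 6 had an adjusted p of 4.56e-09 or below.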

How the results depend on the processing

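The tests chosen only after results had been seen are those with doublets removed at 0.4% per 1000 barcodes, the low-UMI cluster added, genes over 4 times higher in another class left out, cycling progenitor-like clusters alone, clustering without genes that differ between genotypes, glial clusters made without division genes, and the total without microglia-like and unnamed cells. For genes named in the lineage, 1151 of 1235 comparisons with an alternative kept the direction and the side of the threshold, 31 lost the call, 11 gained one and 42 changed sign. Many of the sign changes were in genes near 0 such as pcna, mki67, cdk1, hmga1a, sox2 and mdka. For gene lists the numbers were 148 of 188, with 11 lost, 10 gained and 19 turned. Leaving out 1 library left 6095 to 7400 genes called in the lineage, where the lone library of a genotype is assumed to vary like those of the other. Both genotypes have 2 libraries, which may be technical repeats, and the counts of called genes in microglia-like, ganglion-like, oligodendrocyte-like, rod-like and rod precursor-like cells moved by over 1.5 times when a library was left out. Unless said otherwise, the cause of a change was not tested.

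With no doublets removed, 11979 genes were called in the lineage. The log2 folds were 0.48 for opn1sw1, −0.091 for pcna, −0.041 for mki67, −0.067 for cdk1, −0.052 for sox2, −0.11 for mdka and 0.14 for the share of cycling cells. With doublets removed at 0.4% per 1000 barcodes they were −0.13 for pcna, −0.0602 for mki67, −0.011 for top2a, −0.081 for cdk1, −0.058 for sox2, −0.10 for mdka, 0.11 for the cycling share and −0.11 for the oligodendrocyte-like share. A minimum fold of 1.5 left 1661 genes, since small changes no longer counted. Thinning each cell to 1000 UMIs left 1850 genes of 11892 tested, with log2 folds of 0.011 for mcm5, −0.063 for mki67, 0.057 for hmga1a and 0.55 for insm1a. Thinning lowered the number of UMIs, left out shallower cells and gave each cell the same weight, and these were not tested apart. Leaving out genes over 4 times higher in another class gave 4727 called genes among fewer tested, 0.040 for hmga1a and an adjusted p of 0.485 for the Notch list, with its direction turned. The log2 fold of hmga1a turned to 0.0026 at resolution 2, to 0.0042 with the low-UMI cluster added and to 0.0026 when clustered without genes that differ between genotypes.

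In the Müller glia-like clusters alone, 4670 genes were called. The log2 folds were −0.93 for pcna, −1.47 for mki67, −1.65 for top2a, −0.96 for cdk1, −0.26 for ccnd1, 0.014 for hmga1a, 0.82 for insm1a, −0.11 for sox2, −0.00767 for stat3 and −0.12 for mdka. Lists that turned there had camera adjusted p-values of 3.04e-12 for DNA replication and for mitosis, 0.721 for cell cycle regulators and 0.0364 for rod markers. With an estimated correlation, the DNA replication, mitosis and rod marker lists did not pass there. In cycling progenitor-like clusters alone, the log2 folds were −0.040 for pcna and mki67, −0.044 for cdk1, 0.084 for glula and −0.26 for il34. The lists that turned there had adjusted p-values of 0.859 for DNA replication and retina regeneration, 0.439 for mitosis and 0.715 for Müller glia identity and the Notch pathway. In glial clusters made without division genes, 13 lists were called by camera with the preset correlation. Those that turned against the lineage had adjusted p-values of 0.245 for Notch, 0.308 for glycolysis, 3.54e-07 for ribosome biogenesis and 0.905 for extracellular matrix. Ribosome biogenesis did not pass in these clusters with an estimated correlation. With an estimated correlation, 0 of the 8 lists called in the lineage were called.

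For shares of cells, the cycling class had a log2 fold of −0.31 at resolution 2 and of −0.31 when rod-like and cone-like cells were left out of the total. It was −0.18 with a minimum of 500 genes, −0.25 with microglia-like and unnamed cells left out of the total and 0.22 with TMM over classes. TMM over classes also gave 0.16 for horizontal-like and 0.59, now called, for oligodendrocyte-like cells, resolution 2 gave 0.58 for neutrophil-like cells, no longer called (adjusted p = 0.0530), and clustering without genes that differ between genotypes gave −0.0064 for oligodendrocyte-like cells. DESeq2 called 5166 genes in the lineage (5119 of them shared), 4281 in amacrine-like, 2693 in bipolar-like, 2907 in cone-like, 553 in ganglion-like, 2281 in horizontal-like, 1156 in rod-like and 101 in rod precursor-like cells. The interaction with rod-like cells alone called 2438 genes.

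The replicate numbers do not pair the libraries, and same-numbered libraries had correlations of deviations of −0.03, −0.03 and −0.05 in the lineage, over all cells and in the other cells. With the replicate number as a block, 7418 genes were called in the lineage, 7284 of them shared, and 658 in oligodendrocyte-like cells.

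Leaving out each library in turn gave ranges of log2 fold from −0.015 to 0.10 for cdk1, −0.070 to 0.058 for hmga1a, −0.47 to 0.12 for insm1a, −0.044 to 0.13 for mki67, −0.065 to 0.071 for pcna and −0.32 to 0.14 for csf1ra in microglia-like cells. For shares the ranges were −0.17 to 0.021 for cycling, −0.17 to −0.11 for horizontal-like and 0.12 to 0.45 for oligodendrocyte-like cells, where 0.45 was a gained call. Called genes ranged from 689 to 1703 in ganglion-like, 964 to 3093 in microglia-like, 142 to 3313 in oligodendrocyte-like, 2116 to 2834 in rod-like and 136 to 417 in rod precursor-like cells. Adjusted p-values ranged from 0.257 to 1.00 for DNA replication, 0.662 to 0.941 for Notch, 0.0837 to 1.00 for mitosis and 0.896 to 1.00 for retina regeneration.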

Other observations

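The tests chosen only after results had been seen were those of the bipolar-like share against horizontal-like cells and with no barcodes removed, the direction of the level in rod-like cells, clustering without genes that differ between genotypes, and glial clusters made without division genes. Oligodendrocyte-like cells were rare (85 and 75 cells in WT, 94 and 118 in mutants), yet 949 genes were higher and 609 lower of 10666. The called genes came to 3313 without WT replicate 1 and to 142 and 198 without mutant replicate 1 or 2. Mitosis genes were higher there for 14 of 45 and lower for 0 (27 and 0 adjusted over the list alone; median log2 fold 2.38, camera adjusted p = 1.75e-11; adjusted p = 0.433 with an estimated correlation). Extracellular matrix genes were higher for 10 of 37 and lower for 1 (14 and 1 adjusted over the list alone; median 2.91, camera adjusted p = 3.45e-06; adjusted p = 0.433 with an estimated correlation). The class was not uniform, and at resolution 2 it had a cluster led by ecrg4a, mbpa and the collagen gene col1a2, with 25 and 28 WT and 48 and 61 mutant cells. Clustered without genes that differ between genotypes, cells with ecrg4a, col1a2 and col1a1b formed a mural/fibroblast-like cluster of 3 and 0 WT and 22 and 26 mutant cells, and the matrix genes were not tested apart from such cells. The annexin gene anxa1a rose from 15.17 CPM ± 0.163 to 156.5 ± 5.70 (log2 fold 3.36, SE 0.17, adjusted p = 0.00100, edgeR quasi-likelihood), and the microfibril gene mfap2 with a log2 fold of 5.65. The lysosomal protease gene ctsba fell (−3.16), as did cbln4 (−5.43) and the autophagy receptor gene sqstm1 (−2.92). The gene tph1b, an enzyme of serotonin synthesis, had 1 and 0 UMIs in WT against 136 and 233 in mutants.

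Genes of glycolysis and hypoxia rose in bipolar-like cells, 22 of 36 with 4 lower (22 and 4 adjusted over the list alone; median 0.37, camera adjusted p = 8.21e-06; adjusted p = 0.401 with an estimated correlation). They also rose in rod-like cells, 15 of 35 with 3 lower (16 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.00113; adjusted p = 0.677 with an estimated correlation). In bipolar-like cells interferon response genes were higher for 27 of 31 and lower for 1 (28 and 1 adjusted over the list alone; median 1.76, camera adjusted p = 7.94e-12). Immediate early and heat shock genes were higher for 25 of 41 and lower for 4 (26 and 4; median 0.44, camera adjusted p = 4.24e-06). With an estimated correlation both lists had an adjusted p of 0.297. Ribosome biogenesis genes, lower in the lineage, were higher in bipolar-like cells for 26 of 53 and lower for 1 (27 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.508 with an estimated correlation). The difference between the classes was not tested. Over all cells, mitosis genes were lower for 57 of 64 and higher for 0 (57 and 0 adjusted over the list alone; median −0.40, camera adjusted p = 1.28e-08; adjusted p = 0.762 with an estimated correlation). This sum also carries the change in cell classes.

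Division genes were lower in mutants in the Müller glia-like clusters alone, while the lineage as a whole and the cycling clusters showed no such shift. The cycling clusters were named from division genes, so the lack of a shift there is not an independent measure of division. The DNA replication and mitosis lists did not pass in the Müller glia-like clusters with an estimated correlation. In edgeR's test of single genes, mcm5, mki67, top2a and cdk1 were called lower in these clusters. By that test pcna (adjusted p = 0.154) and ccnb1 (0.211) were not called. Free RNA of cycling cells was tested on the fall in the summed level of the 2 lists, from 3522 CPM ± 329 to 2122 ± 512. That fall was 0.724 times the level in WT rod-like cells, within the bound set for that explanation. The bound cannot decide the size, because CPM were compared between cells of unlike depth. Median depths in WT were 1339 and 1409 UMIs in rod-like and 13093 and 13831 in Müller glia-like cells. A like number of free UMIs per cell would be fewer CPM in the deeper cells. The level in rod-like cells was 148 CPM higher in mutants (1934 ± 18.6 in WT and 2082 ± 19.4), a reading added after the size had been seen. This goes against less free RNA, but the make-up of the rod-like class also differed between genotypes. Its largest cluster was cluster 6 in WT and cluster 11 in mutants. With no barcodes removed as doublets, the mean of the medians of the 2 lists moved by 0.11 towards 0, to −0.81. This met the bound set against doublets, but it covers only barcodes that Scrublet scored high. Doublets that it missed were in both settings, so the test cannot decide on them. The border between glial and cycling clusters stays open, since medians in glial clusters made without division genes were 1.30 for mitosis and 0.53 for DNA replication, which met neither bound set beforehand, and a difference in how glia of the mutants enter the cycle was not tested separately from it.

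A set of 12 genes changed over 2-fold the same way in all 10 tested classes, 6 higher and 6 lower, among them ctsba, phb2a and spartb, all lower, and 0 of them on the interferon list. Counts of exosc3 went in opposite ways for 2 entries of the same name (ENSDARG00000098334 with a lineage log2 fold of 3.03 and ENSDARG00000104246 with −4.64), so reads shared between near-identical copies or a strain difference between the fish may be involved. Of the 6 genes with a position, 2 (33.3%) had another of them within 10 genes, against a mean of 0.423% in random sets (permutation p = 0.0128), which met the bound set for haplotype blocks, and the share near the mutated loci was 0 times that among all genes. Both tests are void, because only 6 of the 12 genes had a position. Whether the mutants came from another background than the WT fish stays open.

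Bipolar-like, amacrine-like and ganglion-like cells took larger shares in mutants. A smaller number of other cells in the total would raise all classes of unchanged number alike. The log2 folds of bipolar-like and horizontal-like cells differed by 1.54 (SE 0.0565), so these 2 classes did not both keep their number. Shares alone cannot decide more, because horizontal-like cells may be among the cells that became fewer. Doublet removal and genotype differences in the clustering genes are argued against, as the bipolar-like log2 fold was 1.37 with no barcodes removed and 1.39 when clustered without genes that differ between genotypes. The yield of each class in dissociation was not tested and stays open, as does a difference in the survival of inner retinal neurons after NMDA, so both remain possible explanations.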
